A study of Homo sapiens with 12 samples.

How the data were processed

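PolyA RNA had been sequenced from 12 libraries of the human glioblastoma line U87, 2 for each combination of line (parental or resistant to JQ1, per the labels) and 24 h treatment (DMSO, 1000 nM JQ1 or 1000 nM dBET6). The deposited estimated counts per transcript are kallisto's, per the submitters' processing notes and the file headers, and were not normalized. The deposited TPM values in the same files are kallisto's relative transcript abundances, per the file headers. The deposited FPKM values are 1 table of genes for all 12 libraries, made with kallisto and DESeq2 on genome build hg19 per the submitters' processing notes, which do not say how these were combined. Versions of these tools are not given in the sources used here.

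Each file held 196354 transcripts, of which 92.6% were paired with genes through GENCODE release 29, a newer annotation than the files use. The paired transcripts took 94.7% to 96.2% of the counts of a library and fell into 52271 of the 57773 genes of the FPKM table. The pairing was tested on 10511 genes with an FPKM above 1 in every library. For 82.0% of them the TPM summed over paired transcripts, with a factor per library removed, lay within 1% of the deposited FPKM, and for 5.85% it lay below 0.8 of it. Among the genes named, BCL2L1, BRD2, BRD3, LTBP2, CWC22, MTSS1 and NBEA were rebuilt in part (0.74, 0.92, 0.89, 0.93, 0.76, 0.79 and 0.89 of the deposited value) and SYT16 at 3.00 times that value, so their levels are less certain than their errors say. Current symbols were matched for 99.4% of gene identifiers, and symbols are printed as the files give them. FCGR1A, PSG4 and several histone genes have near-identical paralogs, between which kallisto divides reads.

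Estimated counts were summed per gene and rounded. The libraries held 36486809 and 34619742 estimated counts for parental DMSO, 36602910 and 31346557 for parental JQ1, 29041636 and 24768861 for parental dBET6, 40388589 and 33617240 for resistant DMSO, 33710124 and 35512170 for resistant JQ1, and 24732177 and 27679190 for resistant dBET6. Genes kept by edgeR's filterByExpr (19093) were scaled by TMM and tested with edgeR's quasi-likelihood test (version 4.0.16, robust, R 4.3.3). All 12 libraries were in 1 fit with a mean per group and 6 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Compared were each compound with DMSO in each line, both compounds in each line, the lines in DMSO, the response to each compound between the lines, and the dBET6 minus JQ1 contrast between the lines. The biological coefficient of variation was 7.88%. Intervals on ratios and the floor of 3 counts per library cover counting error only, and other intervals cover 95%.

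Sensitivity was simulated with 200 changed genes, far fewer than observed, so shares may differ. For JQ1 in parental cells 71.6%, 94.0% and 98.5% of 1.5-, 2- and 4-fold changes were recovered. For response differences between lines the shares were 26.9%, 82.1% and 97.0% for JQ1 and 37.3%, 70.1% and 97.0% for dBET6. False calls were 3.95% to 11.6% of calls over the 9 comparisons.

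The comparisons, tests, thresholds, 31 gene lists, 7 lists of cell type markers, the rule for naming genes and all alternatives except those named as added were chosen before the data were examined. Lists with at least 5 tested members were tested with limma's camera (3.58.1) on log2 CPM (prior count 2) at a preset correlation of 0.01, and also with an estimated correlation and with fry, adjusted over 279 tests. Named were, for each compound against DMSO and for the lines in DMSO, the 6 largest and 6 smallest log2 fold changes among protein-coding genes past the threshold with a mean of at least 10 CPM and no overlap of the libraries. For dBET6 against JQ1 and for differences between the lines the number was 4 each way, without the separation for the latter. Also named were 12 genes in every comparison (among them MYC, HEXIM1, SERPINI1, BRD2, BRD3, CRBN, E2F1, CDKN1A, BCL2L1, CDK6 and CCND1) and at most 4 members per list, those with the smallest p in the direction of the list's test. The text prints part of them, and some genes that the rule names are not reported here.

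Alternatives were DESeq2's median-of-ratios size factors in edgeR, total counts, scaling to the 13 mitochondrially encoded mRNAs, DESeq2's Wald test (1.42.0), no filter beyond 1 count, a mean of at least 10 CPM, length-scaled TPM counts, limma-trend on log2 TPM (pseudocounts 1 and 0.1) and on log2 FPKM (pseudocount 1) with a mean of at least 1, only the libraries compared, a replicate block, a fold threshold of 1.5, an adjusted p under 0.01 for overlaps, lists without members held by another list, and leaving out each library. No column and no library was left out of the main tests, and transcripts without a paired gene were not used here. Protein levels and cell growth were not analysed here.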

Results

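RNA was measured in U87, an established human glioblastoma cell line, as a parental culture and as a derivative that the series description calls resistant to JQ1. Both lines were exposed for 24 h to DMSO, the solvent control, to 1000 nM JQ1 or to 1000 nM dBET6. JQ1 occupies the acetyl-lysine pockets of the BET proteins (among them BRD2 and BRD3), which tie acetylated chromatin to transcription. dBET6 joins a JQ1-like ligand to a ligand of cereblon, the substrate receptor of a ubiquitin ligase, so that the BET proteins it binds are marked for degradation. The 6 groups held 2 polyA RNA libraries each, 12 in all. Nothing in the labels states whether the replicates were separate cultures, so the p-values measure only the spread between these libraries.

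The libraries of a group resembled each other, with a Pearson correlation across genes of log2 CPM between 0.982 and 0.994 (genes are not independent replicates), although their differences exceeded counting noise (chi-square per degree of freedom 4.79 to 13.8). The first principal component held 65.4% of the variance and separated the 4 dBET6 libraries from the other 8. The second held 13.9% and separated the lines within each condition. The RNA of the 4 dBET6 libraries also differed in make-up. Transcripts annotated in the ribosomal DNA region took 0.863% to 1.14% of their counts against 0.00341% to 0.0170% in the other 8 libraries. Mitochondrially encoded mRNA took 3.19% to 3.94% against 1.46% to 2.70%, and the 50 most abundant genes took 25.8% to 31.0% against 12.4% to 18.5%. These differences moved with dBET6 and therefore stand beside every gene group given for it.

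Levels are TMM-scaled CPM ± SD and log2 fold changes are ± SE, with n = 2 libraries per group throughout. Each log2 fold change is relative to the bulk of the genes. With scaling to total counts instead, the median gene moved by -0.10 for JQ1 and -0.65 for dBET6 in parental cells, by -0.17 and -1.14 in resistant cells, and by 0.07 between the lines in DMSO. With scaling to mitochondrially encoded mRNA, the same medians were -0.28, -1.78, -0.56, -2.12 and -0.23. The medians of dBET6 against JQ1 were -0.51 and -1.45 under the same scalings in parental cells, and -0.90 and -1.50 in resistant cells. The medians of the differences between the lines were -0.07 and -0.28 for JQ1 and -0.49 and -0.34 for dBET6. Of the 279 tests of 31 gene lists in 9 comparisons, 133 passed with camera at the preset correlation. With an estimated correlation 0 passed after adjustment and 45 had an unadjusted p under 0.05, and with fry 214 passed, so list p-values are given in both forms. The lists of TGF-beta and BMP targets, heat shock and proteasome, drug efflux, neural and glial transcription factors and long neural genes passed in none of the 9 comparisons with camera at the preset correlation and TMM scaling, where their lowest adjusted p-values were 0.107, 0.152, 0.0921, 0.26 and 0.171. Still, TGF-beta and BMP targets passed for JQ1 in resistant cells without members held by another list (adjusted p = 0.00707). Long neural genes passed with mitochondrial scaling between the lines (adjusted p = 0.0235) and for the dBET6 response difference (adjusted p = 0.0293). Other list calls that ended are given at the end, but not all those without 1 library.

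The first comparison asked how parental cells responded to JQ1. HEXIM1 (ENSG00000186834), an inhibitor of the elongation factor P-TEFb, rose from 33.6 ± 5.69 to 194 ± 3.82 CPM (log2 2.53 ± 0.10, adjusted p = 2.96e-17). SERPINI1 (ENSG00000163536), which encodes neuroserpin, rose from 0.976 ± 0.141 to 5.99 ± 0.325 (2.61 ± 0.20, adjusted p = 2.63e-11), and BRD2 (ENSG00000204256) rose by 2.02 ± 0.09. IL1B (ENSG00000125538), an inflammatory cytokine, fell from 27.7 ± 0.982 to 0.519 ± 0.0995 (-5.74 ± 0.16, adjusted p = 1.51e-20), with CCR1, a chemokine receptor (-4.40 ± 0.16), THBD, which encodes thrombomodulin (-3.77 ± 0.14), and SERPINB2 and PLAU, an inhibitor and an activator of plasminogen cleavage (-3.76 ± 0.11 and -3.67 ± 0.11). MYC (ENSG00000136997) rose from 69.3 ± 0.952 to 98.0 ± 2.23 (0.50 ± 0.08, adjusted p = 1.88e-05). In total 4362 genes were higher and 4979 lower of 19093 tested, 1552 and 1834 of them by at least 2-fold.

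Cell cycle genes fell together with JQ1 in parental cells. Of 45 tested G2/M and mitosis genes 43 were lower and 1 higher, with the same counts when adjusted over the list alone (median -1.04, camera adjusted p = 6.37e-19 and adjusted p = 0.243 with an estimated correlation). AURKA, a mitotic kinase, fell from 132 to 38.4 CPM (-1.78 ± 0.09), and TPX2, its activator, fell by 1.51. Of 50 E2F targets and DNA replication genes 46 were lower and 0 higher, 47 and 0 when adjusted over the list alone (median -0.88, adjusted p = 5.14e-17 and adjusted p = 0.243 with an estimated correlation), among them MYBL2 (-1.63 ± 0.10), MCM5 of the replicative helicase (-1.70 ± 0.10) and E2F1 itself (-0.94 ± 0.09). Homologous recombination and Fanconi genes had 26 lower and 2 higher of 34, 26 and 3 adjusted over the list alone (median -0.71, adjusted p = 5.89e-06 and adjusted p = 0.286 with an estimated correlation). FANCD2 was at -1.41 ± 0.10.

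Histone and oxidative stress genes rose. Of 16 tested histone genes 12 were higher and 2 lower, with the same counts when adjusted over the list alone (median 1.72, also 1.72 with the gene that had a group at 0 set to its bound, adjusted p = 1.68e-08 and adjusted p = 0.243 with an estimated correlation). HIST1H2BD rose from 1.40 ± 0.0583 to 56.0 ± 7.29 CPM (5.32 ± 0.14) and HIST2H2BE from 2.93 ± 0.164 to 69.7 ± 2.28 (4.57 ± 0.11). PEG10, a gene derived from a retrotransposon, rose from 162.9 to 3299.7 CPM (4.34 ± 0.10). Of 22 oxidative stress genes 18 were higher and 2 lower, again equal when adjusted over the list alone (median 0.98, adjusted p = 3.27e-09 and adjusted p = 0.243 with an estimated correlation). TXNRD1, a thioredoxin reductase, was at 2.16 ± 0.09 and NQO1, a quinone reductase, at 1.85 ± 0.09. SQSTM1, the autophagy receptor p62, rose by 2.97 ± 0.10, while its list of autophagy and lysosome genes had 22 higher and 6 lower of 43, 23 and 6 adjusted over the list alone (median 0.27, or -0.03 with scaling to mitochondrially encoded mRNA, adjusted p = 0.00183 and adjusted p = 0.418 with an estimated correlation).

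NF-kB and inflammatory genes had 21 lower and 3 higher of 28 with JQ1 in parental cells, 21 and 4 adjusted over the list alone (median -0.97, adjusted p = 0.000105 and adjusted p = 0.243 with an estimated correlation). LIF was at -3.02 ± 0.12 and IL8 at -2.61 ± 0.14. Growth factor receptors and ligands had 16 lower and 3 higher of 31, 16 and 4 adjusted over the list alone (median -0.69, adjusted p = 0.00126 and adjusted p = 0.374 with an estimated correlation). HGF was at -2.88 ± 0.11. Of 44 mesenchymal and extracellular matrix genes 25 were lower and 10 higher, with the same counts when adjusted over the list alone (median -0.45, adjusted p = 0.00231 and adjusted p = 0.527 with an estimated correlation). TNC, which encodes tenascin C, was at -1.61 ± 0.10. Among apoptosis genes 17 were lower and 5 higher of 28, equal when adjusted over the list alone (median -0.48, adjusted p = 0.0299 and adjusted p = 0.396 with an estimated correlation). BCL2L1, an inhibitor of cell death, fell by 1.48, and FAS, a death receptor, fell by 1.52. The share of changed genes that were higher was 46.7%, against 36.5% with scaling to total counts and 21.4% with scaling to mitochondrially encoded mRNA. The rise of CRBN (ENSG00000113851), which encodes cereblon, was small (0.26 ± 0.10, adjusted p = 0.0393) and did not pass without 7 of the libraries in turn, nor with scaling to mitochondrially encoded mRNA, where it was -0.03, and the apoptosis call ended without parental JQ1 1 (adjusted p = 0.0696) or without members held by another list (adjusted p = 0.0996).

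**Figure D1:**
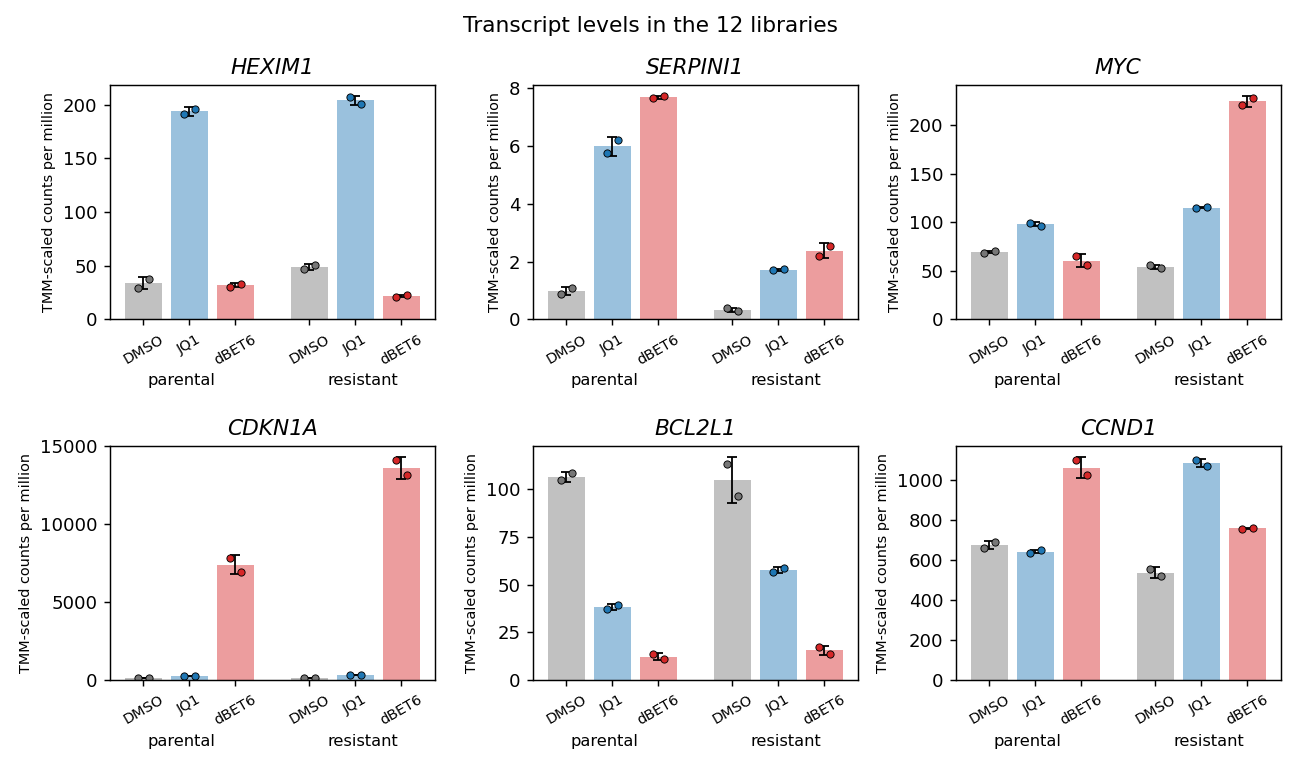
Levels of 6 genes in the 6 groups as TMM-scaled CPM on the vertical axis, with bars for the mean, points for the 2 libraries and error bars for the SD. HEXIM1 was 194 ± 3.82 with JQ1 and 31.7 ± 1.98 with dBET6 in parental cells, CDKN1A was 7396 ± 612 with dBET6 against 128.4 ± 7.89 in DMSO, and MYC with dBET6 was 60.6 ± 6.73 in parental and 224 ± 5.42 in resistant cells, a rise in resistant cells that was -0.02 on the log2 scale with scaling to mitochondrially encoded mRNA.

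With dBET6, parental cells changed more genes and by larger folds. CDKN1A (ENSG00000124762), which encodes the cell cycle inhibitor p21, rose from 128.4 ± 7.89 to 7396 ± 612 CPM (5.85 ± 0.11, adjusted p = 6.94e-25). HEXIM1, in contrast to its rise with JQ1, was 31.7 ± 1.98 against 33.6 ± 5.69 in DMSO (-0.08 ± 0.10, adjusted p = 0.464), or -0.72 and -1.85 with scaling to total counts and to mitochondrially encoded mRNA, and passed as lower without parental DMSO 1 (-0.30) and as higher with a minimum of 10 CPM (0.29, adjusted p = 0.0184). SERPINI1 rose to 7.69 ± 0.0416 (2.97 ± 0.21). BRD3 fell by 1.92 and CRBN fell by 1.47 on the log2 scale, while BRD2 rose by 1.14 ± 0.08, or fell by 0.64 with scaling to mitochondrially encoded mRNA. In total 7066 genes were higher and 7507 lower, 1067 and 174 of them by at least 16-fold.

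Genes near silence in DMSO were among the largest rises with dBET6 in parental cells. C9orf152 rose from 0.0965 ± 0.0712 to 205 ± 13.9 CPM (11.02 ± 0.20, adjusted p = 1.10e-24). FCGR1A, a receptor for immunoglobulin G, had 1 count in the DMSO libraries and 1365 with dBET6, a ratio of 2850.3 with a counting interval of 510.7 to 112663, although its near-identical paralog FCGR1B makes the assignment of reads between them uncertain. CLDN6, a tight junction protein, had 2 and 1457 counts, a ratio of 1521 (420.4 to 12573), and LYZ, which encodes lysozyme, had 2 and 1002, a ratio of 1046 (288.9 to 8650.4). The fitted fold of SYT16 rests on transcripts whose pairing with the gene is uncertain. In the other direction CCR1 fell from 2648 to 2 counts, a ratio of 634 (175 to 5238), TDO2, a tryptophan-degrading enzyme, fell by 6.34, GDF5, a growth factor of the bone morphogenetic protein family, fell by 6.15, and DUSP6, a phosphatase of ERK, fell by 4.92.

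Of 53 cytosolic ribosomal protein genes 53 were higher with dBET6 in parental cells, also when adjusted over the list alone (median 1.26, adjusted p = 6.51e-16 and adjusted p = 0.396 with an estimated correlation), although their median was -0.51 with scaling to mitochondrially encoded mRNA, where RPS9 went from 1.74 to -0.03. G2/M and mitosis genes had 41 lower and 3 higher of 45 (median -2.17, adjusted p = 4.88e-11 and adjusted p = 0.243 with an estimated correlation). AURKA fell from 132 to 7.67 CPM (-4.10 ± 0.11). Homologous recombination and Fanconi genes had 31 lower and 1 higher of 34 (median -2.03, adjusted p = 4.46e-07 and adjusted p = 0.245 with an estimated correlation). TOPBP1 was at -2.48 ± 0.10 and BARD1, the partner of BRCA1, at -2.84 ± 0.15. E2F targets had 36 lower and 8 higher of 50 (median -1.06, adjusted p = 0.000173 and adjusted p = 0.418 with an estimated correlation). RFC4 was at -3.46 ± 0.12, whereas E2F1 was at 0.03 ± 0.09 (adjusted p = 0.791), or -0.61 and -1.75 with scaling to total counts and to mitochondrially encoded mRNA. Histones had 14 higher and 1 lower of 16 (median 3.53, the same with the bound, adjusted p = 7.83e-07 and adjusted p = 0.243 with an estimated correlation). HIST2H2BE was at 6.04 ± 0.11. Each of these lists had the same counts when adjusted over the list alone.

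Of 29 p53 targets 20 were higher and 5 lower with dBET6 in parental cells, equal when adjusted over the list alone (median 0.79, or -0.98 with scaling to mitochondrially encoded mRNA, mean 1.60, adjusted p = 0.000141 and adjusted p = 0.243 with an estimated correlation). BTG2, an antiproliferative gene, rose from 1.00 to 164 CPM (7.36 ± 0.13). Of 22 oxidative stress genes 17 were higher and 3 lower, also adjusted over the list alone (median 1.79, adjusted p = 3.35e-06 and adjusted p = 0.243 with an estimated correlation). HMOX1, which encodes heme oxygenase 1, rose from 195.8 to 2946 CPM (3.91 ± 0.11), and SRXN1, a sulfiredoxin, rose by 5.52 ± 0.10. Genes of BET proteins and transcription elongation had 25 lower and 7 higher of 36, equal over the list alone (median -0.63, adjusted p = 0.00494 and adjusted p = 0.285 with an estimated correlation). MED1 of Mediator was at -3.42 ± 0.11 and CDK12, an elongation kinase, at -2.63 ± 0.09. The cereblon ligase list had 11 lower and 3 higher of 15, equal over the list alone (median -1.21, adjusted p = 0.0197 and adjusted p = 0.527 with an estimated correlation). UBA3 of the NEDD8 pathway was at -2.84 ± 0.13. MHC class I genes had 12 higher and 2 lower of 15, equal over the list alone (median 0.64, or -1.13 with scaling to mitochondrially encoded mRNA, adjusted p = 0.00573 and adjusted p = 0.418 with an estimated correlation), HLA-C with 1.68 ± 0.09 going to -0.09. Nuclear-encoded oxidative phosphorylation genes had 25 higher and 10 lower of 42, equal over the list alone (median 0.49, or -0.14 and -1.28 with scaling to total counts and to mitochondrially encoded mRNA, adjusted p = 0.00867 and adjusted p = 0.675 with an estimated correlation), NDUFA2 of complex I with 1.39 ± 0.09 and COX6A1 of complex IV with 1.38 ± 0.09 going to -0.38 and -0.39.

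Apoptosis genes went both ways with dBET6 in parental cells, 15 lower and 10 higher of 28, also adjusted over the list alone (median -0.73, adjusted p = 0.444 and adjusted p = 0.702 with an estimated correlation). BCL2L1 fell from 106 to 12.2 CPM (-3.12 ± 0.12) and XIAP, an inhibitor of caspases, fell by 2.08, while the death-promoting BBC3 and HRK rose by 3.09 ± 0.13 and 2.01 ± 0.09. Immediate early genes were split as well, 14 higher and 14 lower of 31, also adjusted over the list alone (median 0.10, or -0.54 and -1.68 with scaling to total counts and to mitochondrially encoded mRNA, adjusted p = 0.758 and adjusted p = 0.959 with an estimated correlation). EGR1 was at 4.66 ± 0.11 and FOS at 5.16 ± 0.13. The share of changed genes that were higher was 48.5%, against 30.6% and 11.4% with scaling to total counts and to mitochondrially encoded mRNA, so that a rise given here is a rise relative to other genes. MYC was at -0.19 ± 0.09 (adjusted p = 0.0458), or -0.83 and -1.97 with these scalings. Its call ended with RLE size factors (-0.07, adjusted p = 0.475), with a replicate block, and without parental dBET6 2 (-0.12) or parental DMSO 2 (-0.23). It turned with a minimum of 10 CPM (0.17).

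The third comparison asked how resistant cells responded to JQ1. HEXIM1 rose from 49.0 ± 2.82 to 204 ± 4.09 CPM (2.06 ± 0.10, adjusted p = 2.00e-15), SERPINI1 rose from 0.334 ± 0.0661 to 1.72 ± 0.0272 (2.34 ± 0.26), and BRD2 rose by 2.03 ± 0.09. MYC rose from 54.3 ± 1.98 to 115 ± 0.374 (1.08 ± 0.09, adjusted p = 5.71e-11). CCND1 (ENSG00000110092), which encodes cyclin D1, rose from 537 ± 27.0 to 1083 ± 20.4 (1.01 ± 0.08, adjusted p = 1.16e-10). IL1B again fell, from 141 ± 1.66 to 2.37 ± 0.228 (-5.90 ± 0.12), with LTBP2, a latent TGF-beta binding protein (-3.44 ± 0.11), and TRIM22, an interferon-induced gene (-3.38 ± 0.14). In total 3978 genes were higher and 4413 lower, a higher share of 47.4% that was 28.3% and 6.67% with scaling to total counts and to mitochondrially encoded mRNA.

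In the resistant cells JQ1 lowered 43 of 45 G2/M and mitosis genes and raised 1, also adjusted over the list alone (median -1.09, adjusted p = 1.88e-21 and adjusted p = 0.243 with an estimated correlation). CCNA2, which encodes cyclin A2, was at -1.65 ± 0.09. E2F targets had 42 lower and 0 higher of 50, 44 and 0 adjusted over the list alone (median -0.63, adjusted p = 8.88e-14 and adjusted p = 0.243 with an estimated correlation). Histones had 12 higher and 0 lower of 16, 13 and 0 adjusted over the list alone (median 1.82, the same with the bound, adjusted p = 1.37e-10 and adjusted p = 0.243 with an estimated correlation). HIST2H2BE rose from 3.99 ± 0.332 to 113 ± 1.46 CPM (4.82 ± 0.10). Oxidative stress genes had 15 higher and 2 lower of 22, also adjusted over the list alone (median 0.64, adjusted p = 0.000129 and adjusted p = 0.245 with an estimated correlation). MYC targets and ribosome biogenesis genes had 20 higher and 5 lower of 45, 21 and 6 adjusted over the list alone (median 0.16, or -0.03 and -0.43 with scaling to total counts and to mitochondrially encoded mRNA, adjusted p = 0.00362 and adjusted p = 0.479 with an estimated correlation). With the mitochondrial scaling the call ended (adjusted p = 0.767). ODC1, an enzyme of polyamine synthesis, was at 1.76 ± 0.09 and NOP56, a nucleolar protein, at 0.97 ± 0.08. The same list in parental cells had 21 lower and 5 higher, 22 and 6 adjusted over the list alone (median -0.20, adjusted p = 0.0366 and adjusted p = 0.584 with an estimated correlation), a call that ended without parental DMSO 1 (adjusted p = 0.0605) or parental JQ1 1 (adjusted p = 0.0778).

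Among the other groups in resistant cells, interferon-stimulated genes had 21 lower and 4 higher of 37, also adjusted over the list alone (median -0.51, or -0.50 with the bound, adjusted p = 0.00371 and adjusted p = 0.243 with an estimated correlation). OAS3 was at -1.44 ± 0.10. Mesenchymal genes had 20 lower and 9 higher of 44, 20 and 10 adjusted over the list alone (median -0.16, adjusted p = 0.0071 and adjusted p = 0.563 with an estimated correlation). PLAU was at -2.72 ± 0.10. YAP and TEAD targets had 8 higher and 2 lower of 24, also adjusted over the list alone (median 0.08, or -0.11 and -0.50 with scaling to total counts and to mitochondrially encoded mRNA, mean 0.38, adjusted p = 0.0349 and adjusted p = 0.396 with an estimated correlation). The call ended without members held by another list (adjusted p = 0.274) and with the mitochondrial scaling (adjusted p = 0.104). CTGF, a matricellular growth factor, rose from 3.40 to 22.9 CPM (2.75 ± 0.10). CRBN was at 0.19 ± 0.10 (adjusted p = 0.133), or -0.39 with scaling to mitochondrially encoded mRNA.

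With dBET6, resistant cells raised CDKN1A from 126 ± 0.547 to 13626 ± 701 CPM (6.76 ± 0.11, adjusted p = 8.13e-26) and MYC from 54.3 ± 1.98 to 224 ± 5.42 (2.05 ± 0.09, adjusted p = 1.22e-17), the latter at -0.02 with scaling to mitochondrially encoded mRNA. HEXIM1 fell from 49.0 ± 2.82 to 21.8 ± 1.04 (-1.16 ± 0.11, adjusted p = 1.08e-10), and SERPINI1 rose by 2.81 ± 0.29. ANKRD1, a muscle ankyrin repeat gene, rose from 0.152 ± 0.0118 to 156 ± 11.3 (9.97 ± 0.17), FCGR1A from 0.0778 ± 0.0252 to 113 ± 3.02 (10.47 ± 0.19), and SEMA4A, a semaphorin, from 3 to 2206 counts, a ratio of 2206 with a counting interval of 753.8 to 10705. Among the lower genes were IL1B (-5.78 ± 0.14), LMNB1, which encodes lamin B1 (61.2 ± 1.39 to 1.55 ± 0.338, -5.31 ± 0.14), GDF5 (-5.27 ± 0.14), THBD (-5.01 ± 0.19) and MGA, a partner of MAX (-4.89 ± 0.16). The pairing of transcripts with CWC22 (-5.92 ± 0.50), a splicing factor gene, was incomplete. In total 6813 genes were higher and 7542 lower, 941 and 250 of them by at least 16-fold.

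Ribosomal protein genes were again higher in resistant cells with dBET6, 53 of 53 and the same adjusted over the list alone (median 2.09, or 0.03 with scaling to mitochondrially encoded mRNA, adjusted p = 1.62e-20 and adjusted p = 0.374 with an estimated correlation). RPL8 rose from 1355 to 8980.6 CPM (2.73 ± 0.10). G2/M genes had 42 lower and 3 higher of 45 (median -2.30, adjusted p = 7.37e-11 and adjusted p = 0.243 with an estimated correlation), and recombination and Fanconi genes had 31 lower and 0 higher of 34 (median -2.31, adjusted p = 1.03e-07 and adjusted p = 0.243 with an estimated correlation). BARD1 was at -4.74 ± 0.20. Histones had 13 higher and 1 lower of 16 (median 4.31, the same with the bound, adjusted p = 3.35e-06 and adjusted p = 0.243 with an estimated correlation). HIST2H2BE rose from 3.99 to 950 CPM (7.89 ± 0.11). E2F targets had 40 lower and 9 higher of 50 (median -1.71, adjusted p = 1.47e-05 and adjusted p = 0.396 with an estimated correlation). BET and elongation genes had 27 lower and 7 higher of 36 (median -0.92, adjusted p = 0.00109 and adjusted p = 0.243 with an estimated correlation). BRD3 was at -2.45 ± 0.11, while BRD2 was at 0.86 ± 0.08, or -0.22 and -1.20 with scaling to total counts and to mitochondrially encoded mRNA. These 6 lists had the same counts when adjusted over the list alone.

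Of 29 p53 targets 20 were higher and 6 lower in these cells, also adjusted over the list alone (median 1.45, or -0.62 with scaling to mitochondrially encoded mRNA, adjusted p = 8.44e-05 and adjusted p = 0.243 with an estimated correlation). BTG2 rose from 1.96 to 924 CPM (8.88 ± 0.13). Cholesterol and fatty acid synthesis genes had 23 higher and 7 lower of 33, also adjusted over the list alone (median 0.85, or -0.22 and -1.21 with scaling to total counts and to mitochondrially encoded mRNA, adjusted p = 0.00152 and adjusted p = 0.396 with an estimated correlation). Mesenchymal genes had 23 higher and 14 lower of 44, also adjusted over the list alone (median 0.46, or -0.54 and -1.53 with the same scalings, adjusted p = 0.0327 and adjusted p = 0.625 with an estimated correlation), a call that ended without members held by another list (adjusted p = 0.150) and with the mitochondrial scaling (adjusted p = 0.463). CYR61 was at 4.86 ± 0.10. In the apoptosis list 16 were lower and 7 higher of 28, also adjusted over the list alone (median -0.51, adjusted p = 0.475 and adjusted p = 0.717 with an estimated correlation). BBC3 was at 3.82 ± 0.12 and BCL2L1 at -2.75 ± 0.12. CRBN fell by 2.51 on the log2 scale. The higher share of 47.5% was 22.5% and 8.94% with scaling to total counts and to mitochondrially encoded mRNA, and CCND1 (0.50 ± 0.08) was -0.58 and -1.57 under these scalings.

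**Figure D2:**
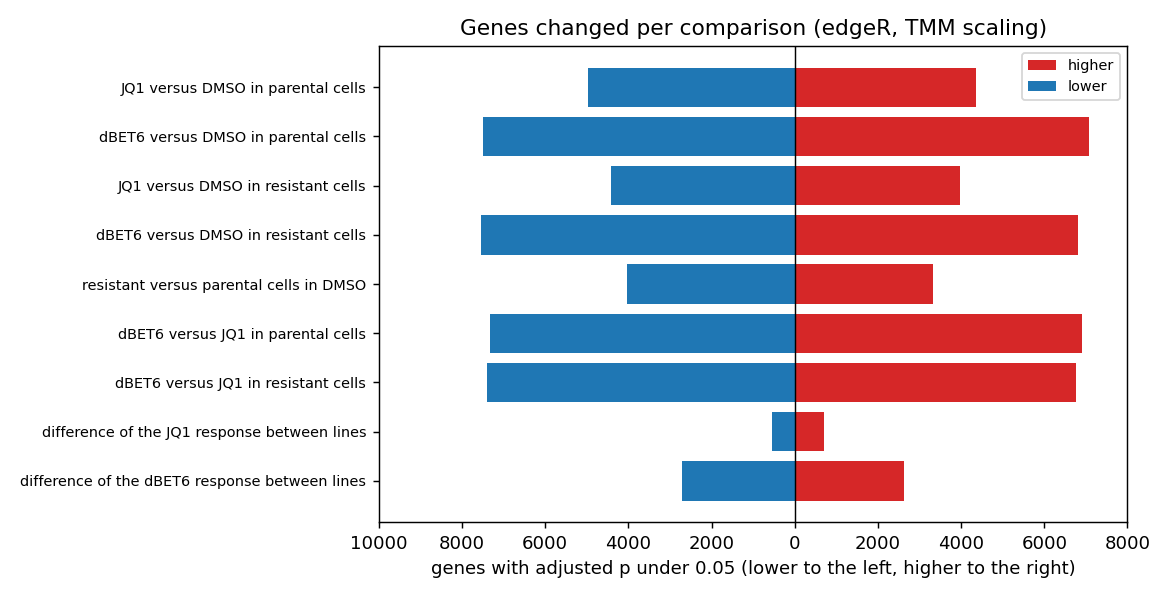
Number of genes with an adjusted p under 0.05 on the horizontal axis, lower genes to the left of 0 and higher genes to the right, for the 9 comparisons (19093 genes tested, 2 libraries per group). JQ1 changed 4362 higher and 4979 lower in parental cells and dBET6 7066 and 7507; the higher shares of 46.7% and 48.5% became 21.4% and 11.4% with scaling to mitochondrially encoded mRNA.

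The resistant line was next compared with the parental line in DMSO. IL13RA2 (ENSG00000123496), a decoy receptor of interleukin 13 encoded on chromosome X, fell from 75.8 ± 6.69 to 0.042 ± 0.0256 CPM (-10.64 ± 0.25, adjusted p = 9.38e-18). PCDH7, a protocadherin, UBE2K, a ubiquitin-conjugating enzyme, and IGFBP7, which binds insulin-like growth factors, all encoded on chromosome 4, were at -7.85 ± 0.20, -7.14 ± 0.18 and -7.37 ± 0.44. TIMP3, an inhibitor of metalloproteases encoded on chromosome 22, fell from 44.8 ± 1.63 to 0.196 ± 0.0063 (-7.81 ± 0.17). Higher in resistant cells were RCN3, a calcium-binding protein of the endoplasmic reticulum (5.34 ± 0.0878 to 40.2 ± 2.06, 2.91 ± 0.10), SLC16A6, a transporter (2.75 ± 0.11), NALCN, a sodium leak channel (2.75 ± 0.14), and PTPRU, a receptor phosphatase (4.42 ± 0.39). In total 3314 genes were higher and 4043 lower, 51 and 194 of them by at least 16-fold.

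Before any compound, several gene groups had more lower than higher members in resistant cells. G2/M and mitosis genes had 35 lower and 0 higher of 45, also adjusted over the list alone (median -0.41, adjusted p = 1.05e-09 and adjusted p = 0.245 with an estimated correlation). CCNA2 was at -1.17 ± 0.09. MHC class I genes had 14 lower and 0 higher of 15, also adjusted over the list alone (median -0.70, adjusted p = 1.22e-09 and adjusted p = 0.243 with an estimated correlation). HLA-B fell from 65.4 to 18.6 CPM (-1.82 ± 0.09). The MHC region of chromosome 6 held the lowest run of 15 genes (median -1.16), and the 5 members on other chromosomes had a median of -0.60, with 4 lower. Hypoxia and glycolysis genes had 23 lower and 4 higher of 34, 26 and 4 adjusted over the list alone (median -0.45, adjusted p = 1.16e-06 and adjusted p = 0.396 with an estimated correlation). PFKL, a phosphofructokinase, was at -1.09 ± 0.09. YAP and TEAD targets had 12 lower and 3 higher of 24, also adjusted over the list alone (median -0.42, adjusted p = 0.00183 and adjusted p = 0.243 with an estimated correlation). Mesenchymal genes had 20 lower and 7 higher of 44, 21 and 9 adjusted over the list alone (median -0.22, mean -0.70, adjusted p = 0.0055 and adjusted p = 0.551 with an estimated correlation). COL5A1, a collagen, was at -3.52 ± 0.12 and LOX, which crosslinks collagen, at -2.24 ± 0.09. Inflammatory genes had 15 lower and 5 higher of 28, also adjusted over the list alone (median -0.52, adjusted p = 0.00703 and adjusted p = 0.243 with an estimated correlation). MMP3, a matrix protease, was at -3.39 ± 0.11. Interferon-stimulated genes had 15 lower and 3 higher of 37, 18 and 7 adjusted over the list alone (median -0.29, adjusted p = 0.0151 and adjusted p = 0.285 with an estimated correlation). IFI44L was at -2.41 ± 0.16.

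Drug targets and transport genes were also compared between lines. HEXIM1 was higher in resistant cells (0.55 ± 0.10), and MYC and SERPINI1 were lower (-0.35 ± 0.09 and -1.52 ± 0.28). BRD2, BRD3 and CRBN were at -0.14 ± 0.08, 0.08 ± 0.09 and 0.15 ± 0.10 (adjusted p = 0.19, 0.518 and 0.278), the last 2 at -0.17 and -0.09 with scaling to mitochondrially encoded mRNA. Drug efflux and metabolism genes had 8 higher and 1 lower of 21, 8 and 2 adjusted over the list alone (median 0.18, or 0.11 with the bound and -0.04 with scaling to mitochondrially encoded mRNA, adjusted p = 0.171 and adjusted p = 0.45 with an estimated correlation). ABCC10 was at 0.59 ± 0.10 and ABCA3 at 1.16 ± 0.23. The higher share of 45.0% was 53.6% and 19.4% with scaling to total counts and to mitochondrially encoded mRNA. CCND1 was lower (-0.33 ± 0.08, adjusted p = 0.00228), a call that ended without resistant DMSO 2 (-0.28, adjusted p = 0.0731).

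JQ1 and dBET6 were compared at the same dose and time within each line. In parental cells HEXIM1 was 194 ± 3.82 CPM with JQ1 and 31.7 ± 1.98 with dBET6 (-2.61 with an interval of -2.82 to -2.40, adjusted p = 4.64e-18), and CDKN1A was 269 ± 5.27 and 7396 ± 612 (4.78, interval 4.57 to 5.00, adjusted p = 4.73e-23). SERPINI1 was at 5.99 ± 0.325 with JQ1 and 7.69 ± 0.0416 with dBET6, a difference of 0.36 with an interval of 0.00 to 0.72 that did not pass after adjustment (adjusted p = 0.0646) and was -1.11 with scaling to mitochondrially encoded mRNA. MYC and CRBN were lower with dBET6 than with JQ1 (-0.69, interval -0.87 to -0.51, and -1.74, interval -1.98 to -1.49), and E2F1 and CCND1 were higher (0.96, interval 0.78 to 1.15, and 0.73, interval 0.56 to 0.90), or -0.51 and -0.75 with scaling to mitochondrially encoded mRNA. C2orf71, a photoreceptor gene, had no count in the JQ1 libraries and was at least 371-fold higher with dBET6 (against 3 counts per library), and IWS1, an elongation factor gene, was lower by -4.41 ± 0.15. In total 6915 genes were higher and 7324 lower with dBET6, a higher share of 48.6% that was 32.9% and 13.1% with scaling to total counts and to mitochondrially encoded mRNA.

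By list in parental cells, p53 targets had 21 higher and 4 lower of 29 with dBET6 (median 1.10, or -0.35 with scaling to mitochondrially encoded mRNA, adjusted p = 5.24e-05 and adjusted p = 0.243 with an estimated correlation). BET and elongation genes had 27 lower and 5 higher of 36, 27 and 6 adjusted over the list alone (median -0.81, adjusted p = 0.000247 and adjusted p = 0.243 with an estimated correlation). MED1 was at -3.45 ± 0.11. Inflammatory genes, which fell with JQ1, had 17 higher and 5 lower of 28 (median 0.65, or 0.57 with the gene that had a group at 0 set to its bound and -0.80 with scaling to mitochondrially encoded mRNA, adjusted p = 0.0181 and adjusted p = 0.244 with an estimated correlation). IL8 rose from 3.52 to 123 CPM (5.12 ± 0.14). Mesenchymal genes had 31 higher and 8 lower of 44, 32 and 9 adjusted over the list alone (median 0.83, or -0.65 with the same scaling, adjusted p = 0.000141 and adjusted p = 0.43 with an estimated correlation). CTGF was at 3.68 ± 0.09. The p53 and inflammatory lists had the same counts when adjusted over the list alone.

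In resistant cells the same contrast gave -3.22 for HEXIM1 (interval -3.45 to -3.00, adjusted p = 1.70e-19), 5.36 for CDKN1A (interval 5.14 to 5.58) and -2.70 for CRBN (interval -2.99 to -2.42). MYC was higher with dBET6 (0.96, interval 0.79 to 1.14, adjusted p = 5.29e-11), or -0.52 with scaling to mitochondrially encoded mRNA, and E2F1 and CCND1 were lower (-0.45, interval -0.64 to -0.26, and -0.51, interval -0.68 to -0.34). SERPINI1 did not pass (0.47, interval -0.00 to 0.95, adjusted p = 0.0687) and was -1.01 with scaling to mitochondrially encoded mRNA. TMEM119, a membrane protein gene, was higher with dBET6 by 8.84 ± 0.19, and NBEA, with incomplete pairing of transcripts, was lower by -4.75 ± 0.53. Recombination and Fanconi genes had 29 lower and 2 higher of 34, also adjusted over the list alone (median -1.90, adjusted p = 1.28e-05 and adjusted p = 0.315 with an estimated correlation), and MHC class I genes had 12 higher and 2 lower of 15, also adjusted over the list alone (median 1.23, or -0.25 with scaling to mitochondrially encoded mRNA, adjusted p = 0.00125 and adjusted p = 0.396 with an estimated correlation). ERAP2, a peptide-trimming protease, was at 2.34 ± 0.10. The cereblon ligase list had 11 lower and 3 higher of 15, 12 and 3 adjusted over the list alone (median -1.09, adjusted p = 0.0228 and adjusted p = 0.536 with an estimated correlation). Immediate early genes had 18 higher and 12 lower of 31, also adjusted over the list alone (median 0.78, or -0.10 and -0.71 with scaling to total counts and to mitochondrially encoded mRNA, adjusted p = 0.0498 and adjusted p = 0.707 with an estimated correlation), a call that ended without resistant dBET6 1 (adjusted p = 0.0572) or members held by another list (adjusted p = 0.662), and with the mitochondrial scaling (adjusted p = 0.226), RLE (adjusted p = 0.0568) or a replicate block (adjusted p = 0.0518). In total 6767 genes were higher and 7401 lower, a higher share of 47.8% that was 26.2% and 14.3% under these scalings.

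**Figure D3:**
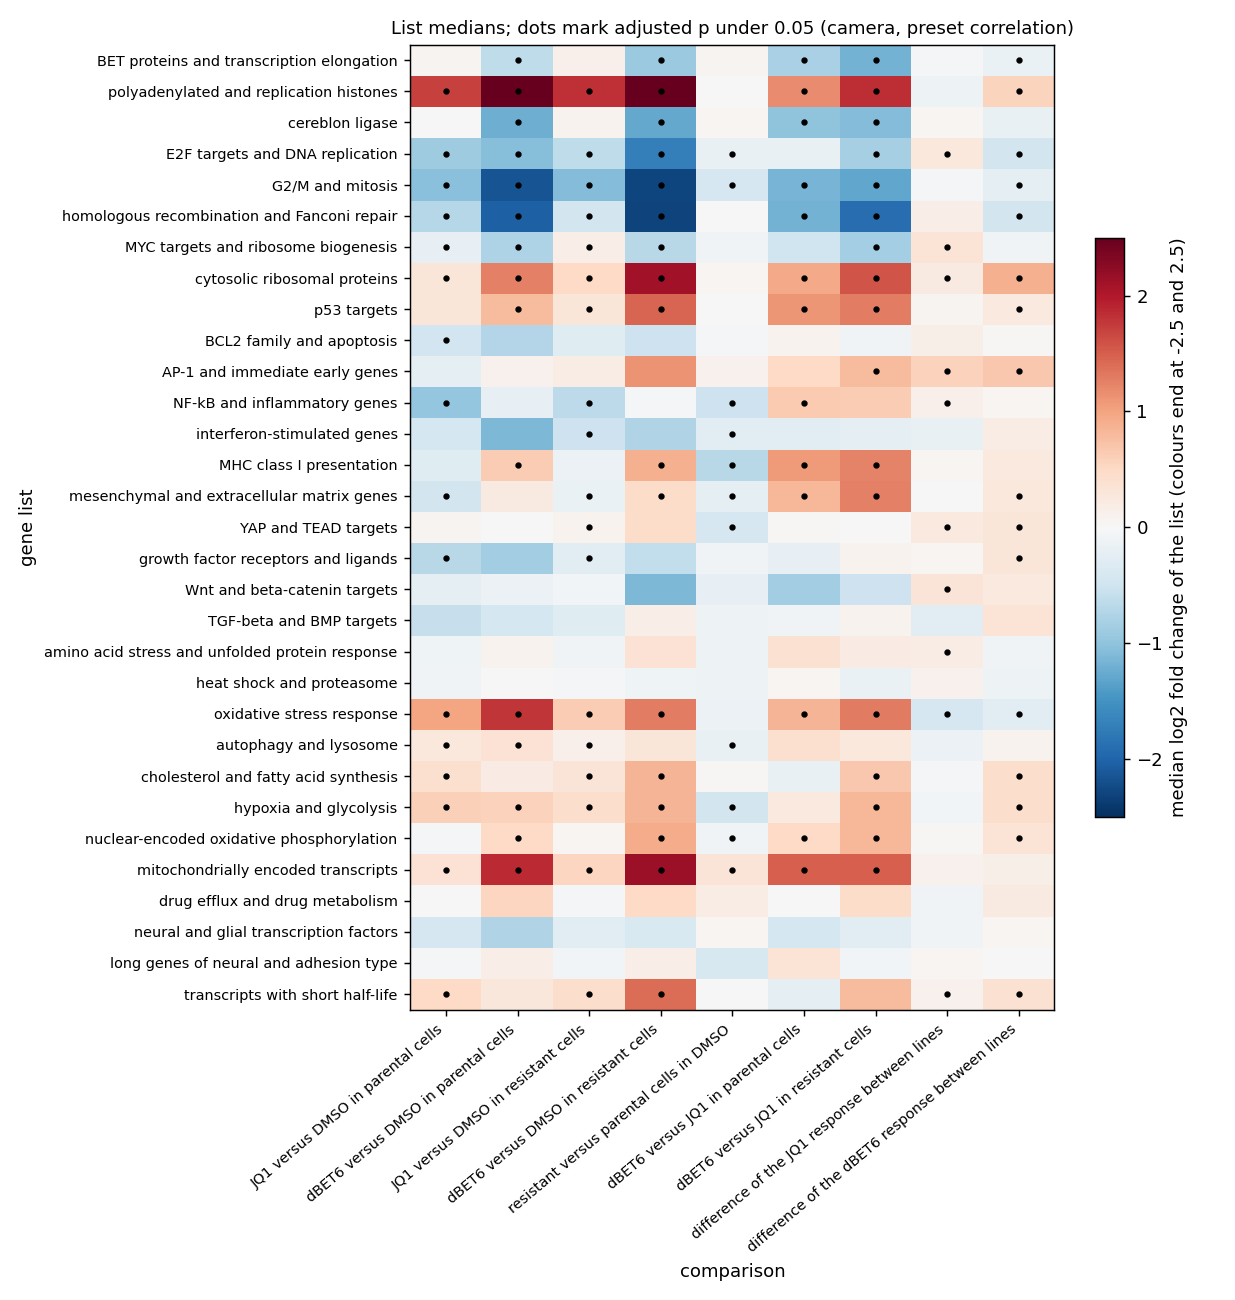
Median log2 fold change of the tested genes of each of 31 lists (vertical axis) in the 9 comparisons (horizontal axis), as colours that end at -2.5 and 2.5, with a dot where camera's adjusted p was under 0.05 at the preset correlation (0 of 279 with an estimated correlation). Histones were at 1.72 and 3.53 with JQ1 and dBET6 in parental cells and G2/M genes at -1.04 and -2.17, while ribosomal protein genes were at 0.30 and 1.26, or -0.01 and -0.51 with scaling to mitochondrially encoded mRNA.

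The design also asks whether the resistant line answered each compound differently, tested as the response in resistant cells minus that in parental cells. For JQ1, 692 genes had a higher and 549 a lower response in resistant cells. CCND1 differed by 1.08 (interval 0.84 to 1.32, adjusted p = 6.59e-07), from -0.07 ± 0.08 in parental to 1.01 ± 0.08 in resistant cells, and MYC by 0.58 (interval 0.34 to 0.83, adjusted p = 0.00271). LIF, a cytokine of the interleukin 6 family, and METTL7B, a methyltransferase, differed by 1.86 ± 0.15 and 1.61 ± 0.13, and MMP1, which encodes a collagenase, by 3.07 ± 0.18. PTGES, a prostaglandin synthase, and TNFAIP2 differed by -1.59 ± 0.12 and -2.76 ± 0.26. The responses of SERPINI1 and BRD2 did not differ past the threshold (intervals -1.03 to 0.47 and -0.22 to 0.26).

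MYC targets and ribosome biogenesis genes had a higher JQ1 response in 20 and a lower one in 0 of 45, 27 and 0 adjusted over the list alone (median 0.34, adjusted p = 1.57e-18 and adjusted p = 0.243 with an estimated correlation). NOP56 was at 0.68 ± 0.12. Immediate early genes had 18 higher and 3 lower of 31, also adjusted over the list alone (median 0.58, adjusted p = 7.86e-12 and adjusted p = 0.285 with an estimated correlation). SPRY2, an inhibitor of growth factor signalling, was at 1.15 ± 0.12. Oxidative stress genes had 10 lower and 0 higher of 22, 15 and 0 adjusted over the list alone (median -0.43, adjusted p = 4.26e-12 and adjusted p = 0.243 with an estimated correlation). NQO1 was at -1.06 ± 0.12 and GCLM, of glutathione synthesis, at -1.38 ± 0.16. Inflammatory genes had 6 higher and 1 lower of 28, 7 and 3 adjusted over the list alone (median 0.12, or -0.16 with scaling to mitochondrially encoded mRNA, adjusted p = 0.0225 and adjusted p = 0.245 with an estimated correlation), a call that ended without parental DMSO 2 (adjusted p = 0.0682). The total of 1241 genes was 548 without resistant DMSO 2, 610 without resistant JQ1 2, 645 without resistant DMSO 1, 714 without resistant JQ1 1, 739 without parental DMSO 1 and 805 without parental JQ1 1, and the higher share of 55.8% was 39.1% and 17.3% with scaling to total counts and to mitochondrially encoded mRNA. BCL2L1 (0.62) did not pass without resistant DMSO 2 (0.51) or resistant JQ1 2 (0.57), and HEXIM1 (-0.47, adjusted p = 0.0319) did not pass without any 1 of 7 libraries (-0.30 without parental DMSO 1, -0.52 without resistant DMSO 1, and -0.41 to -0.49 without parental JQ1 1 or 2, resistant JQ1 1 or 2 or resistant DMSO 2).

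For dBET6 the lines differed in 5333 genes, 2617 with a higher and 2716 with a lower response in resistant cells. MYC differed by 2.24 (interval 1.99 to 2.49, adjusted p = 3.67e-13), from -0.19 ± 0.09 in parental to 2.05 ± 0.09 in resistant cells. HEXIM1 differed by -1.08 (interval -1.38 to -0.78), E2F1 by -1.08 (interval -1.34 to -0.81), CRBN by -1.03 (interval -1.42 to -0.64) and CDKN1A by 0.91 (interval 0.65 to 1.18). METTL7B differed by 4.03 ± 0.13, UBE2K, near absent from resistant cells in DMSO, by 4.78 ± 0.34, and CSF3, a granulocyte growth factor, by -3.27 ± 0.18. SERPINI1, CCND1 and CDK6 did not differ past the threshold (intervals -0.96 to 0.63, -0.40 to 0.08 and -0.17 to 0.75).

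Ribosomal protein genes had a higher dBET6 response in resistant cells, 52 higher and 0 lower of 53, 53 and 0 adjusted over the list alone (median 0.89, adjusted p = 2.90e-29 and adjusted p = 0.251 with an estimated correlation). Cholesterol synthesis genes had 17 higher and 0 lower of 33, 18 and 0 adjusted over the list alone (median 0.44, adjusted p = 2.52e-09 and adjusted p = 0.243 with an estimated correlation). Immediate early genes had 18 higher and 1 lower of 31, also adjusted over the list alone (median 0.68, adjusted p = 3.86e-07 and adjusted p = 0.396 with an estimated correlation). KLF10 was at 2.29 ± 0.12. E2F targets had 27 lower and 4 higher of 50, 28 and 5 adjusted over the list alone (median -0.47, adjusted p = 3.29e-05 and adjusted p = 0.396 with an estimated correlation). CDC6 was at -1.44 ± 0.15. Oxidative stress genes had 9 lower and 3 higher of 22, also adjusted over the list alone (median -0.28, adjusted p = 0.0055 and adjusted p = 0.396 with an estimated correlation). GCLM was at -2.56 ± 0.16. The higher share of 49.1% was 12.2% and 14.2% with scaling to total counts and to mitochondrially encoded mRNA. For p53 targets, 11 higher and 4 lower of 29, 12 and 6 adjusted over the list alone (median 0.25, or -0.19 and -0.03 under these scalings, adjusted p = 0.0245 and adjusted p = 0.396 with an estimated correlation). TP53I3 was at 2.57 ± 0.16, the call ended without parental dBET6 1 (adjusted p = 0.0555) or resistant dBET6 1 (adjusted p = 0.0641). The difference between the lines in the contrast of dBET6 with JQ1 passed for 5751 genes, 2791 higher and 2960 lower, a higher share of 48.5% that was 17.6% and 45.7% with scaling to total counts and to mitochondrially encoded mRNA.

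Responses were compared across the 19093 genes. The JQ1 responses had a Pearson r of 0.585 and a Spearman rho of 0.685, with 2898 genes higher in both lines against 909 by the product of the counts over the genes, 3483 lower in both against 1151, and 98 opposite. The dBET6 responses had r of 0.862 and rho of 0.881, with 5768 higher in both against 2521, 6560 lower in both against 2965, and 285 opposite. JQ1 and dBET6 within a line share the 2 DMSO libraries, which cannot be split. In parental cells r was 0.408 (rho 0.393) against 0.415 in 20 simulations with no true change, with a covariance of 0.993 against 0.0692, and 2195 genes were higher with both compounds against 1614, 3303 lower with both against 1958, and 2168 opposite. In resistant cells r was 0.35 (rho 0.318) against 0.370, with a covariance of 0.763 against 0.0646, and 1914 were higher with both against 1419, 2766 lower with both against 1743, and 2287 opposite. With no true change r holds only shared noise and is not comparable with the observed r. Shared controls may add to the excess, which these simulations (at most 0.3 genes) cannot measure.

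**Figure D4:**
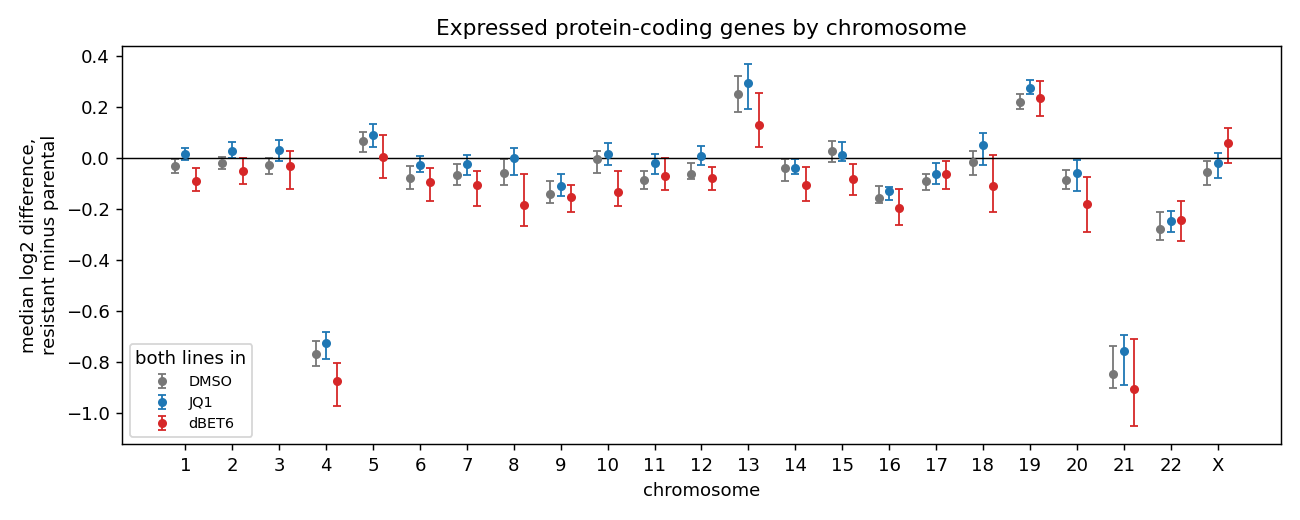
Median log2 difference of resistant minus parental cells (vertical axis) for the expressed protein-coding genes of each chromosome (horizontal axis) in DMSO, JQ1 and dBET6 libraries, with error bars for the 95% interval of 1000 resamples of the genes. Chromosomes 4 and 21 were at -0.77 and -0.85 in DMSO, and chromosomes 13 and 19 at 0.25 and 0.22, the latter at 0.01 and -0.03 with scaling to mitochondrially encoded mRNA.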

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

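Of the tests in this part, those of background RNA, of leukocytes, of the scaling in the ribosomal pattern and of less noise were chosen only after the result was seen. The genes and lists given first were singled out because the lines differed in a test of their responses to a compound (log2, resistant minus parental, adjusted p under 0.05). The 3 patterns weighed after them were noticed in the data. Of 19093 genes 1241 differed for JQ1, 5333 for dBET6 and 5751 for dBET6 minus JQ1. Some genes counted below were named because they differed.

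For JQ1, 35 of 74 named genes differed. These 22 were higher: MMP1 3.07, LIF 1.86, TIMP3 1.70, METTL7B 1.61, SERPINB2 1.55, MAFF 1.49, GADD45A 1.28, IL8 1.19, CTGF 1.18, SPRY2 1.15, KLF6 1.12, CCND1 1.08, PLAU 0.95, EREG 0.92, HGF 0.86, LYAR 0.80, THBD 0.77, WDR74 0.75, ODC1 0.72, NOP56 0.68, BCL2L1 0.62 and MYC 0.58. These 13 were lower: TNFAIP2 -2.76, PSG4 -2.38, PTGES -1.59, MCF2L -1.59, GCLM -1.38, AKR1C1 -1.35, NQO1 -1.06, AQP9 -1.04, PEG10 -0.94, TXNRD1 -0.75, HIST1H2AC -0.60, ADM -0.48 and HEXIM1 -0.47. BCL2L1 and HEXIM1 lost their calls in leave-outs, as the report lists. Called list medians were AP-1 and immediate early genes 0.58, MYC targets 0.34, Wnt targets 0.32 and oxidative stress -0.43. Others turned with scaling to mitochondrially encoded mRNA: E2F targets 0.26 (-0.02), YAP targets 0.25 (-0.04), ribosomal proteins 0.23 (-0.04), amino acid stress 0.19 (-0.09), inflammatory genes 0.12 (-0.16) and transcripts with short half-life 0.10 (-0.18). Without 1 library the calls ended for inflammatory genes (parental DMSO 2, adjusted p = 0.0682), short half-life (parental DMSO 2, adjusted p = 0.104; resistant JQ1 2, adjusted p = 0.0604) and amino acid stress (parental JQ1 1, adjusted p = 0.0916; resistant JQ1 2, adjusted p = 0.0994). Without members held by another list they ended for Wnt targets (adjusted p = 0.163), amino acid stress (adjusted p = 0.0575) and short half-life (adjusted p = 0.882), and with the mitochondrial scaling for E2F targets (adjusted p = 0.0651), amino acid stress (adjusted p = 0.368) and short half-life (adjusted p = 0.438).

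For dBET6, 57 of 93 named genes differed. These 30 were higher: RASD2 5.18, UBE2K 4.78, PLEKHA6 4.63, METTL7B 4.03, CCR1 3.05, SPRY2 2.87, TP53I3 2.57, ANKRD1 2.42, KLF10 2.29, MYC 2.24, GDF15 1.85, HIST2H2BE 1.85, TDO2 1.72, ZMYND8 1.59, BTG2 1.52, CYR61 1.46, FDXR 1.45, ABCA1 1.45, DHCR7 1.44, KLF6 1.41, RPL8 1.08, RPL12 1.06, RPS9 0.94, PPM1D 0.92, COX6A1 0.92, CDKN1A 0.91, NDUFA2 0.88, GDF5 0.87, BBC3 0.72 and HRK 0.61. These 27 were lower: FBXW10 -4.12, ZBTB41 -3.46, CSF3 -3.27, NECAB2 -3.15, C9orf152 -2.99, CWC22 -2.66, GCLM -2.56, IL1B -2.21, AKR1C1 -2.08, BARD1 -1.90, E2F2 -1.76, EXO1 -1.49, CDC6 -1.44, MGA -1.41, LMNB1 -1.41, OSGIN1 -1.38, SRXN1 -1.29, MYBL2 -1.22, HEXIM1 -1.08, E2F1 -1.08, CRBN -1.03, TP53INP1 -0.79, CDK12 -0.72, RFC4 -0.66, AURKA -0.57, BRD3 -0.53 and CAND1 -0.47. Called list medians that kept their direction in all scalings were ribosomal proteins 0.89, AP-1 and immediate early genes 0.68, histones 0.56, hypoxia 0.45 and cholesterol synthesis 0.44 (both 0.01 with total counts), BET proteins and elongation -0.16, G2/M -0.22, oxidative stress -0.28, recombination and Fanconi repair -0.45 and E2F targets -0.47. Others turned with scaling to total counts: short half-life 0.38 (-0.06), oxidative phosphorylation 0.35 (-0.09), YAP targets 0.31 (-0.13), growth factors 0.30 (-0.14), mesenchymal genes 0.27 (-0.14) and p53 targets 0.25 (-0.19, and -0.03 with mitochondrially encoded mRNA). Calls ended without parental dBET6 1 for BET proteins (adjusted p = 0.0911), histones (adjusted p = 0.0841) and p53 targets (adjusted p = 0.0555), without resistant dBET6 1 for histones (adjusted p = 0.0841), p53 targets (adjusted p = 0.0641) and G2/M (adjusted p = 0.243), without parental DMSO 2 for histones (adjusted p = 0.0807) and G2/M (adjusted p = 0.137), and without parental dBET6 2 (adjusted p = 0.0665) or resistant DMSO 1 (adjusted p = 0.0746) for G2/M. The G2/M call also ended with RLE size factors (adjusted p = 0.0871), with a replicate block (adjusted p = 0.0534) and without members held by another list (adjusted p = 0.0519), as did p53 targets without such members (adjusted p = 0.0893). With the mitochondrial scaling the calls of histones (adjusted p = 0.0522) and growth factors (adjusted p = 0.0707) ended. With camera's estimated correlation 0 of the 26 lists passed after adjustment.

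The first pattern weighed was that genes near silence in DMSO (below 0.1 CPM) rose with dBET6. Of 1686 tested in parental and 1467 in resistant cells, 838 and 680 rose at least 16-fold, 505 in both, among them genes of leukocytes. Background RNA or DNA would raise all silent genes. The mean of 344 olfactory receptor genes was 0.991% and 1.59% of the median rising protein-coding gene. This argues against it, but rising genes were picked for their rise. Leukocytes would bring PTPRC, TYROBP, AIF1, LAPTM5 and CD3E. The highest of these reached 0.850% and 1.04% of the mean of FCGR1A, LYZ, CD14 and ITGAM, although FCGR1A alone was at 33.9 and 113 CPM, so leukocytes are excluded. Read-through from an expressed gene upstream cannot be told apart from activation. The upstream neighbour lay on the same strand for 68.2% of rising and 59.2% of other genes in parental cells (odds ratio 1.48, interval 1.10 to 1.99) and for 65.2% and 58.3% in resistant cells (1.34, interval 0.993 to 1.81), and the intervals reach both sides of the ratio of 1.5 set for a cause. BET protein degradation may raise such genes, but that was not tested. Depth, polyA selection and RNA content per cell moved with dBET6 or were not measured.

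The second pattern was that ribosomal protein genes were higher with dBET6 and genes of recombination repair lower, with a difference of list medians of 3.30 in parental and 4.40 in resistant cells. A trend with transcript length may contribute, since random lists matched on length and expression differed by 2.07 and 3.00 (medians), but the observed difference exceeded the upper end of matched pairs (2.62 and 3.59) by at least 0.67. Length is excluded as the whole cause, with the limit that the genes matched to ribosomal ones were expressed 0.89 (log2) lower. Reads moved from pseudogenes are excluded, since ribosomal protein pseudogenes rose (their fall was -0.43% of the genes' gain or less). The test of scaling decides nothing, since a factor per library moves all genes alike (lowest difference 3.28 under 4 scalings). The ribosomal genes alone turned in parental cells with scaling to mitochondrially encoded mRNA (1.26 to -0.51). Stability of mRNA during a loss of transcription may contribute and was not tested.

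The third pattern was that the lines differed in more genes for dBET6 than for JQ1. Scaling is excluded as the cause (the ratio of the counts was at least 4.30 under 4 scalings), as is a single library (at least 3.10 with each left out) and lower noise (the median standard error for dBET6 was 1.23 times that for JQ1). The larger size of the dBET6 response may account for the ratio, and this was not tested. The line difference itself, which the design names, stays open as well.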

How the results depend on the processing

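The fit without the dBET6 libraries and all alternatives for the dBET6 minus JQ1 contrast between the lines were added after seeing the data, and the others were planned. Over 346 log2 fold changes of named genes and their alternatives (8762 comparisons), 8545 stayed on their side of the threshold (69 of them with another sign where neither value passed), 131 lost the call, 41 gained one and 45 turned. Where no cause is given below, the cause was not tested.

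Counts of changed genes stayed within 1.5 times their main value under size factors, total counts, DESeq2, no filter and the fit to the compared libraries alone. With a mean of at least 10 CPM only 8853 genes were tested and fewer could pass: 5835 and 7730 for JQ1 and dBET6 in parental cells, 5548 and 7869 in resistant cells, 4620 between the lines, and 7711 and 7889 for dBET6 against JQ1 in parental and resistant cells. A fold threshold of 1.5 asks for more than a change and left 3463 and 2588 genes for JQ1 in parental and resistant cells, 1974 between the lines, 104 and 1097 for the differences of the JQ1 and dBET6 responses, and 1323 for the contrast. With FPKM the counts were 6224 and 5528 for JQ1, 4046 between the lines, and 315 and 3528 for the differences. With TPM they were 4547 (pseudocount 1) and 3713 (0.1) between the lines and 388 and 260 for the JQ1 difference. Length-scaled counts gave 352 and 3517 for the differences. Scaling to mitochondrially encoded mRNA gave 335 and 2727, and 2005 for the contrast.

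Leaving out 1 library, with the lone library of that group assumed to vary like the other groups, kept 4124 of 4152 named values on their side (26 with another sign), with 19 calls lost, 9 gained and 0 turned. The count for the JQ1 difference ranged from 548 (without resistant DMSO 2) to 1493 (without parental dBET6 1) around 1241. Many leave-out values compare no group of the library left out, which pads the shares of 4152 and 8762 that stayed. A lone library makes the filter keep more genes (20130 to 20423 against 19093), which alters the scaling. MYC with dBET6 in parental cells was at -0.36 to -0.12, and from -0.25 to -0.24 without libraries of groups outside that comparison against -0.19. Without the 4 dBET6 libraries 156 of 158 values stayed on their side (3 with another sign), 2 calls were gained, and the JQ1 difference was 1695 genes.

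These named genes turned where at least 1 of both values passed. Scaling to mitochondrially encoded mRNA gave CRBN -0.028 for JQ1 in parental cells. For dBET6 in parental cells it gave BRD2 -0.64, E2F1 -1.75, CCND1 -1.12, RPS9 -0.029, HLA-C -0.095, NDUFA2 -0.38 and COX6A1 -0.39, and in resistant cells MYC -0.023, BRD2 -1.20 and CCND1 -1.57. For dBET6 against JQ1 it gave SERPINI1 -1.11, E2F1 -0.51 and CCND1 -0.75 in parental and MYC -0.52 and SERPINI1 -1.01 in resistant cells. Scaling to total counts turned E2F1 (-0.61) in parental and BRD2 (-0.22) and CCND1 (-0.58) in resistant cells with dBET6. With TPM (pseudocounts 1 and 0.1) the values with dBET6 were BRD2 -0.16 and -0.16, E2F1 -1.32 and -1.33, CCND1 -0.52 and -0.52, NDUFA2 -0.066 and -0.067 and COX6A1 -0.10 and -0.10 in parental cells, and BRD2 -0.70 and -0.72 and CCND1 -0.89 and -0.89 in resistant cells. Against JQ1 they were SERPINI1 -0.70 and -0.82, E2F1 -0.22 and -0.22 and CCND1 -0.14 and -0.14 in parental, and MYC -0.51 and -0.52 and SERPINI1 -0.65 and -1.10 in resistant cells. The shift of the median gene under each scaling is given in the report. With at least 10 CPM, MYC was 0.17 and HEXIM1 0.29 for dBET6 in parental cells.

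Of 279 list tests 133 passed with camera at the preset correlation. With fry, where 214 passed, 9 lists had the other direction: inflammatory genes (adjusted p = 0.000561) and long genes (0.0409) for dBET6 in parental cells, drug efflux for JQ1 (0.0463) and inflammatory genes for dBET6 (0.0352) in resistant cells, and, for dBET6 against JQ1, BCL2 family (0.00381), heat shock (0.0362), long genes (0.0220) and short half-life (0.00847) in parental and BCL2 family (0.00895) in resistant cells. Camera ranks a list against other genes and fry tests it against 0. With mitochondrial scaling 230 stayed on their side, 32 lost the call, 11 gained it and 6 turned: autophagy (adjusted p = 0.631), hypoxia (0.868) and oxidative phosphorylation (0.371) for dBET6 in parental cells, oxidative phosphorylation for dBET6 in resistant cells (0.988) and against JQ1 in parental cells (0.648), and cholesterol synthesis against JQ1 in resistant cells (0.868). Size factors ended 4 calls and added 2, and leaving out members shared with another list ended 10 and added 3. Those given neither in the report nor with the responses of the lines are listed here. Without shared members the call of short half-life for dBET6 in resistant cells ended (adjusted p = 0.606), and immediate early genes for JQ1 (0.00574) and short half-life against JQ1 (0.0254) in parental cells were gained. Size factors ended MYC targets for dBET6 (adjusted p = 0.0634) in resistant cells and oxidative phosphorylation between the lines (0.0562), and gained amino acid stress against JQ1 in parental (0.0380) and autophagy for dBET6 in resistant cells (0.0446). The mitochondrial scaling ended, for JQ1, autophagy (adjusted p = 0.113), cholesterol synthesis (0.0674), ribosomal proteins (0.115) and mitochondrially encoded mRNA (0.0903) in parental cells, and autophagy (0.812), cholesterol synthesis (0.112), hypoxia (0.0927) and p53 targets (0.240) in resistant cells. For dBET6 it ended MHC class I in parental cells (0.913), and MHC class I (0.821), cholesterol synthesis (0.796), hypoxia (0.346) and short half-life (0.0519) in resistant cells. Against JQ1 it ended MHC class I (0.213), inflammatory genes (0.0545), ribosomal proteins (0.0799), oxidative stress (0.108) and histones (0.0876) in parental cells, and MHC class I (0.140), hypoxia (0.649), oxidative phosphorylation (0.527) and oxidative stress (0.0877) in resistant cells, and between the lines mitochondrially encoded mRNA (0.0712). It gained, for JQ1, immediate early (adjusted p = 0.0416) and interferon genes (0.0397) in parental and apoptosis genes (0.0397) in resistant cells, growth factors for dBET6 in parental cells (0.0235), MYC targets (0.000974), E2F targets (0.0474) and cholesterol synthesis (0.0414) against JQ1 in parental cells, amino acid stress between the lines (0.0155) and autophagy in the JQ1 difference (0.0431).

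The overlaps moved under 2 settings. Scaling to mitochondrially encoded mRNA, which counts most genes as lower with dBET6, gave 460 genes higher with JQ1 in both lines (r = 0.56), 1062 higher and 12884 lower with dBET6 in both lines, 349 higher and 5368 lower with both compounds in parental cells, and 187 and 7741 in resistant cells (r = 0.38). With at least 10 CPM 2252 genes were lower with JQ1 in both lines (r = 0.88), 3228 higher and 3706 lower with dBET6 in both lines (r = 0.94), and 1752 and 1668 lower with both compounds in parental and resistant cells (r = 0.38 in resistant cells). These correlations are across genes, which are not independent.

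The replicate numbers share only a number, since the deviations of same-numbered libraries had correlations of -0.06 to 0.06 over 15 pairs of groups. A replicate block gave 9189, 14492, 8276, 14265, 7151, 14155, 14101, 1145, 5200 and 5619 genes in the order of the report. It ended the calls of MYC with dBET6 in parental cells (-0.20) and of the immediate early and G2/M lists, as given beside them, and changed no other call of a named gene or list.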

Other observations

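Of the tests in this part, that of chance among chromosomes was chosen only after the result was seen.

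Genes of chromosomes 4 and 21 were lower in the resistant line. In DMSO the median was -0.77 over 430 expressed genes of chromosome 4 (interval -0.82 to -0.72, 94.9% below 0) and -0.85 over 115 of chromosome 21 (interval -0.90 to -0.74, 93.0% below 0). Chromosomes 13 and 19 had 0.25 and 0.22, and chromosome 22 had -0.28. A candidate explanation is fewer copies of chromosomes 4 and 21. It needs the shift in the other libraries too, and the medians were -0.73 and -0.76 with JQ1 and -0.87 and -0.91 with dBET6. Shuffles of single genes (lowest median -0.22 in 1000) treat neighbours as independent and cannot exclude chance. DNA was not measured, and other causes of a shift along a whole chromosome were not tested. Runs of 15 genes were highest on chromosome 5 (1.35, SPEF2 to DAB2) and lowest in the MHC region of chromosome 6 (-1.16, NOTCH4 to HLA-DOA). Between the MHC class I genes there, 85 other expressed genes had a median of -0.20.

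Loss of DNA was also tested for 194 genes at least 16-fold lower in the resistant line. For a part it is excluded, since 22 of them reached 0.5 of the parental DMSO level in resistant cells with dBET6 (16 with scaling to total counts and 12 to mitochondrially encoded mRNA). Of the 22, 11 were below 0.13 CPM in parental DMSO and 3 were pseudogenes, while 16 others than pseudogenes held at least 10 counts in the resistant dBET6 libraries. For the 120 genes that stayed below 0.1 of it in every resistant group it cannot be told. Their 226 expressed neighbours had a median of -0.21 (interval -0.34 to -0.14), which lies in the range set beforehand against a loss. That range was wrong, because a median near 0 can hold a lower part: 44 neighbours (19.5%) were below -1 against 6.38% of expressed genes (odds ratio 3.71, interval 2.58 to 5.23). The shift of chromosomes 4 and 21, which held 19 of the 120 genes, feeds this ratio. Outside them 28 of 190 neighbours (14.7%) were below -1 against 5.07% (odds ratio 3.24, interval 2.07 to 4.91), and a loss may be smaller than the space between genes. Of the 120 genes, 31 kept at least 10 counts in the resistant DMSO libraries.

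Small nuclear RNA genes were higher with dBET6 in 30 of 35 cases in each line (median 3.40 and 4.53). Long intergenic RNA genes had 658 higher and 197 lower of 1401 in parental cells (median 0.94, or -0.81 with scaling to mitochondrially encoded mRNA) and 618 and 195 in resistant cells (0.86, or -0.20 and -1.18 with total counts and mitochondrially encoded mRNA). Small nucleolar RNA genes had 7 and 11 higher of 34 with JQ1 in parental and resistant cells.

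Markers of other cells moved with dBET6 as follows (higher and lower in parental, then in resistant cells, of those tested): neural stem spheres 4 and 1, 6 and 1 of 7; leukocytes 3 and 0, 4 and 0 of 4; epithelium 2 and 2, 2 and 0 of 5; neurons 3 and 2, 3 and 2 of 8; oligodendrocytes 2 and 3, 2 and 2 of 5; endothelium 3 and 2, 2 and 2 of 6; fibroblasts 1 and 2, 1 and 2 of 6.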
